A study of Mus musculus with 89 samples.

How the data were processed

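RNA-seq counts of 6 libraries from V6.5 mouse embryonic stem cells with an FKBP-V tag on H2afz were analysed, 3 labelled control and 3 labelled dTAG. Samples were placed in groups by their titles, and the columns of the count table were matched to samples by the same titles. The other 83 samples of the series (ChIP-seq, ChIP-nexus, NET-seq, ATAC-seq) are not analysed here.

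The authors deposited whole-number counts per gene, not normalized, in a single table of 27179 features. Per the labels' protocols, RNA was purified on columns, ERCC spike-in RNA was added before library preparation, and libraries were sequenced as paired ends on a NextSeq. The labels describe the libraries as stranded and depleted of ribosomal RNA but name a kit for messenger RNA. RNAs without a poly(A) tail were abundant. The ribosomal RNA precursor Rn45s took 14.1% of the counts in the controls (mean) and 12.1% in dTAG replicate 1. Replication-dependent histone genes took 2.40% (mean) and 2.57%. These shares argue against selection of RNA by its poly(A) tail in the controls and dTAG replicate 1. Per the submitters' processing notes, the tools were STAR 2.7.2b, featureCounts, edgeR and limma with build mm10; their roles, settings and the gene annotation are not given in the sources used here. Whether counting used the strand is also not given, so reads of overlapping and antisense genes could not be told apart. The table held 0 features named as ERCC spike-ins, so the library sizes rest on the genes themselves and a change in total RNA per cell could not be measured.

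Features without a gene name, 903 of them, were left out of library sizes and tests. They held 2.20%, 2.37% and 2.33% of the counts in control replicates 1, 2 and 3 and 2.33%, 6.67% and 14.6% in dTAG replicates 1, 2 and 3. The named genes numbered 26276. Of their symbols, 95.5% matched the RefSeq gene table of assembly GRCm38.p6, which was used for gene type, chromosome and span only, and no coordinates are given. Total counts are given in the report. A count of 0 allows up to 3 counts, which is 0.211, 0.192 and 0.213 CPM in the control libraries and 0.232, 1.41 and 1.66 CPM in dTAG replicates 1, 2 and 3.

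Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, two-sided, without the robust option, design of group alone), with TMM normalization, filterByExpr at its defaults (minimum count 10, minimum total count 15) and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. The TMM factors were 0.789, 0.727 and 0.734 for the controls and 0.774, 1.23 and 2.49 for dTAG replicates 1, 2 and 3, and the common dispersion was 0.424. Standard errors of log2 fold changes were taken from the fold change and the F statistic. CPM are counts per 1000000 counts in named genes. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, over the 31 lists with at least 5 tested members, with an estimated correlation and fry beside it. The 32 lists covered H2A.Z genes and remodellers, other histones, pluripotency, lineages and other cell types, signalling, transcription factors, cell cycle, stress, metabolism, ribosomes, mitochondria, interferon, imprinting, feeder cells and RNA quality. Lists, tests, alternatives and the rule for named genes were fixed before the data were examined.

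Genes are named by that rule: H2afz and H2afv; up to 10 genes in each direction with an adjusted p under 0.05, of which there were 0; the 5 genes with the smallest p in each direction, leaving out names of Gm or LOC with digits, names ending in Rik, names with AC, AL, BC or RP and digits, and -ps pseudogenes; and per list up to 4 members past the threshold or, with none, the 2 most abundant, of which the text gives examples. Genes named for other reasons, such as Wtap, Brd7, Nanog, Trappc9, Muc19 and Sbsn, were chosen after their values were seen.

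Steps added after the data were seen dealt with dTAG replicates 2 and 3. Counts in 1430 olfactory and vomeronasal receptor genes, which these cells do not use, gave the part of another library that looked like dTAG replicate 3: 0.347 of its counts in dTAG replicate 2, or 29.5% of that library, and 0.0913 of its counts in dTAG replicate 1, or 1.28%. From this and the control levels, the predicted share of such counts in dTAG replicate 2 was computed for each gene, and genes under 10% (and, more widely, 20%) were tested without dTAG replicate 3. A gene silent in the controls and high in dTAG replicate 3 is left out by this rule, whether its counts are background or not. The 3 controls were also set against dTAG replicate 1 alone.

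The alternatives were RLE scaling, library totals without composition correction, no filter on low counts, a filter of 1 CPM in all 3 libraries of a group, DESeq2 1.42.0, limma-voom, the robust option, a replicate block, an adjusted p under 0.01, glmTreat against a fold change of 1.5, and leaving out each library in turn. Settings that use ERCC totals or GC content were not run, since there were no ERCC features and no genome sequence was used. Shares and figures were computed with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

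The fits were tested on simulated counts for these libraries, with the controls' means, a dispersion of 0.02 and 200 changed genes. Without background, the 6-library dTAG against control fit (15897 genes) recovered 93% of 100 genes changed 2-fold and all 100 changed 4-fold, with 7 false calls. With counts of the kind in dTAG replicate 3 mixed into dTAG replicates 2 and 3 as measured (16509 genes), it recovered 0% of those changed 2-fold and 0% of those changed 4-fold. In the same simulation, dTAG replicate 1 against the 3 controls (16735 genes) recovered 68% of those changed 2-fold and all of those changed 4-fold, with 7 false calls. In the simulation without background, that fit (16627 genes) recovered 50% of those changed 2-fold and all of those changed 4-fold, with 3 false calls. Background was mixed only into libraries that this fit leaves out, so its shares of 68% and 50% differ by the random draw alone. The common dispersion of those 4 libraries was 0.105, and simulated at that value for every gene (16751 genes) the fit recovered 0% of those changed 2-fold and 26% of those changed 4-fold, with 2 false calls. With the dispersion trend of those libraries over abundance (17102 genes) it recovered 68% and 94%, with 10 false calls. Of the genes at 10 to 100 CPM it then recovered 59.5% of 79 changed 2-fold and 92.6% of 81 changed 4-fold, and of those at 100 CPM or more all 21 and all 19. Genes under 10 CPM were not among the changed ones.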

Results

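The series profiled V6.5 cells, a male mouse embryonic stem cell line, grown in medium that holds them in the naive state (LIF with inhibitors of MEK and GSK3). The series follows depletion of the histone variant H2A.Z.1 by ChIP-seq, ChIP-nexus, NET-seq, ATAC-seq and RNA-seq, in 89 samples. In the RNA-seq cells the gene H2afz, which encodes H2A.Z.1, carries an FKBP-V tag, through which the dTAG molecule sends the protein to the proteasome. The values analysed here are RNA-seq counts per gene in 3 control and 3 dTAG libraries, and the other 83 samples are not analysed here. The comparison asks which transcripts change in level after H2A.Z.1 is depleted. The length of the dTAG treatment is not given for these RNA samples in the sources used here.

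The libraries were of very unequal depth. The controls held 14565322, 16033011 and 14427884 counts and dTAG replicate 1 held 13214351, against 2284068 in dTAG replicate 2 and 2121183 in dTAG replicate 3. Every pair of libraries differed by more than sampling noise, with a chi-square per gene of at least 9.82, so none was a copy of another. Nothing in the labels says that the RNA libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

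The transcripts of both H2A.Z genes were present in all 6 libraries. H2afz stood at 85.5 ± 9.0 CPM (counts per 1000000 counts in named genes; SD, n = 3) in the controls and at 107, 56.3 and 35.9 CPM in dTAG replicates 1, 2 and 3. Its log2 fold change over all 6 libraries was -0.77 (SE 0.74, adjusted p = 0.487, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). H2afv, which encodes H2A.Z.2, stood at 51.9 ± 11.2 CPM (SD, n = 3) in the controls and at 48.0, 36.1 and 25.4 CPM in the dTAG libraries, with a log2 fold change of -0.997 (SE 0.60, edgeR adjusted p = 0.357). The dTAG molecule acts on the protein, so the level of the transcript does not check whether H2A.Z.1 was depleted.

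dTAG replicates 2 and 3 held counts in genes that embryonic stem cells do not use. Olfactory and vomeronasal receptor genes, which serve the sense of smell, had a count in 10.8%, 10.8% and 17.6% of their 1430 members in the controls and in 23.1% in dTAG replicate 1. In dTAG replicate 2 this share was 71.3% (Wilson 95% interval 68.9% to 73.6%) and in dTAG replicate 3 it was 97.1% (96.1% to 97.8%). As a share of counts, the receptor genes took 0.239% in dTAG replicate 2 and 0.811% in dTAG replicate 3, against a control mean of 0.00515%. Abundant RNAs of the cell were scarce in dTAG replicate 3: the mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 took 6.97% ± 0.144 (SD, n = 3) of the counts in the controls, 6.94% in dTAG replicate 1, 4.94% in dTAG replicate 2 and 0.165% in dTAG replicate 3. The 89 cytosolic ribosomal protein genes took 4.03% ± 0.0662 (SD, n = 3) in the controls, 4.24% in dTAG replicate 1, 2.19% in dTAG replicate 2 and 0.223% in dTAG replicate 3. Across genes, the rank correlation with the controls was 0.946 to 0.951 for dTAG replicate 1, 0.955 to 0.959 between controls, 0.839 to 0.847 for dTAG replicate 2 and 0.563 to 0.572 for dTAG replicate 3. Genes are not independent replicates, and the intervals on shares cover counting error only.

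**Figure D1:**
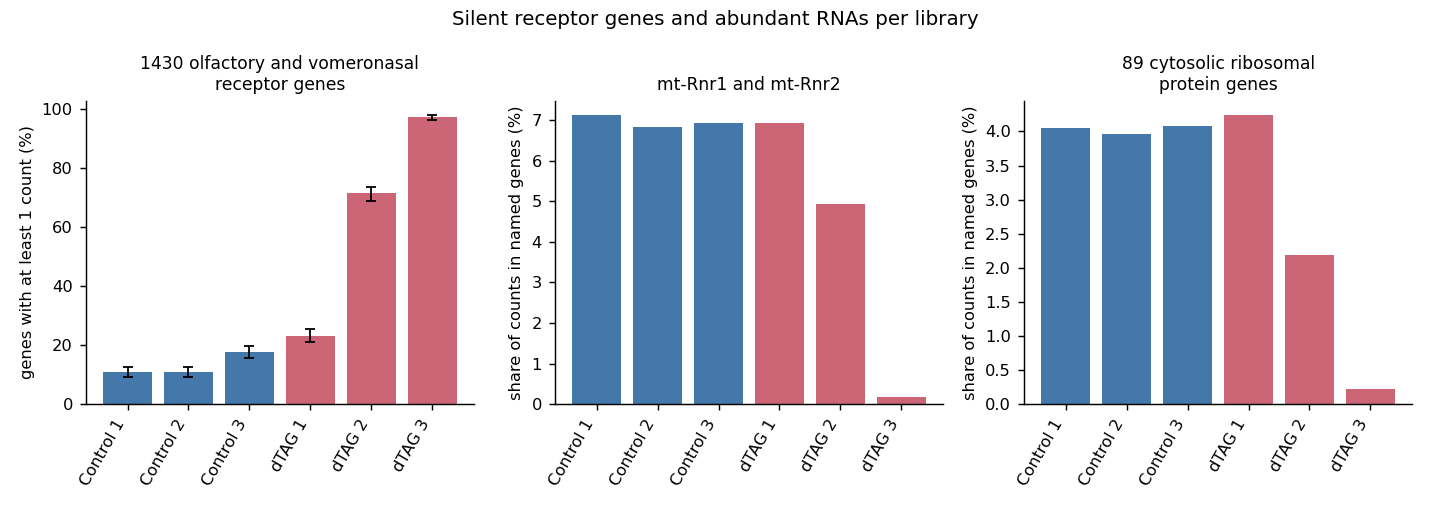
Share of olfactory and vomeronasal receptor genes with at least 1 count (left, bars with Wilson 95% intervals) and share of counts in mitochondrial ribosomal RNA (middle) and in ribosomal protein genes (right), one bar per library, controls in blue and dTAG libraries in red. The receptor share is 23.1% in dTAG replicate 1 and 97.1% in dTAG replicate 3, while mitochondrial ribosomal RNA takes 0.165% in dTAG replicate 3 against 6.94% in dTAG replicate 1.

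Over all 6 libraries no gene was called changed between dTAG and control. Of 18116 genes tested, 0 were higher and 0 were lower at an adjusted p under 0.05 (edgeR), with 4202 at an unadjusted p under 0.05. In simulated counts with background mixed into dTAG replicates 2 and 3 as measured, this fit recovered 0% of genes changed 2-fold or 4-fold. A count of 0 is thus no evidence that levels were unchanged. The higher genes with the smallest p were nearly silent in the controls. Degs2, which encodes a sphingolipid desaturase and hydroxylase, stood at 0.555 ± 0.294 CPM (SD, n = 3) in the controls and at 10.6, 24.4 and 86.6 CPM in the dTAG libraries (log2 fold change 5.01, SE 0.68, edgeR adjusted p = 0.0795). Col4a3, a basement membrane collagen chain, had 0.588 ± 0.148 CPM (SD, n = 3) in the controls and 7.28, 31.0 and 83.9 CPM in the dTAG libraries. Fer1l4, Clhc1 and AU022793 shared this adjusted p and were likewise at under 1 CPM in every control, apart from Clhc1 at 1.15 CPM in control replicate 2 and Fer1l4 at 1.05 CPM in control replicate 1. The lower genes with the smallest p were Speer4cos, Wdfy1, Dnajc24, AI987944 and Lpl, the last encoding lipoprotein lipase. Speer4cos had 14.4 ± 2.66 CPM (SD, n = 3) in the controls and 5.58, 7.51 and 4.97 CPM in the dTAG libraries (log2 fold change -1.86, SE 0.54, edgeR adjusted p = 0.0964). Dnajc24 had 10.4 ± 1.36 CPM (SD, n = 3) and 2.48, 7.51 and 6.07 CPM, and Lpl had 14.2 ± 2.87 CPM (SD, n = 3) and 6.90, 9.38 and 13.8 CPM. Wdfy1 had 29.1 ± 2.62 CPM (SD, n = 3) and 15.3, 22.5 and 43.0 CPM, so it was above every control in dTAG replicate 3, and its log2 fold change of -1.02 rests on the TMM scaling.

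This count of 0 rested on which libraries, tools and filter on low counts were used. DESeq2, run without that filter on 25668 genes, called 5086 (5070 higher, 16 lower). edgeR without its filter on low counts called 1398 of the same 25668 genes, all higher. limma-voom with the filter called 0 of 18116, so DESeq2 differs from the main fit in both tool and filter. edgeR without dTAG replicate 1 called 13222 genes (8839 higher, 4383 lower). Of the 5086 DESeq2 calls, 1 lay among the 1774 tested genes in which counts of the kind seen in dTAG replicate 3 were predicted to make up under 10% of dTAG replicate 2, a choice that leaves out genes with few counts in the controls and many in dTAG replicate 3. Without dTAG replicate 1, 893 of 1624 such genes were called. Their share was predicted for dTAG replicate 2 only, and that fit keeps dTAG replicate 3, where RNAs abundant in the controls were scarce. These calls are thus not from libraries nearly free of such counts. The median log2 fold change of all tested genes was 0.16 with edgeR's TMM scaling and 1.20 with library totals alone, so medians of gene groups over the 6 libraries are given below relative to the median of all tested genes. In dTAG replicate 2 the abundant RNAs of the controls were kept in part. The ribosomal RNA precursor Rn45s took 13.7% of the counts, against 14.1% ± 2.43 (SD, n = 3) in the controls. Other abundant RNAs fell: mitochondrial ribosomal RNA took 4.94% against a control mean of 6.97%, and ribosomal protein genes took 2.19% against 4.03%. In dTAG replicate 3 Rn45s took 0.604%, so RNA of the controls' composition was not the main part of that library. What made up the rest is not settled, and every value over the 6 libraries rests on it.

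**Figure D2:**
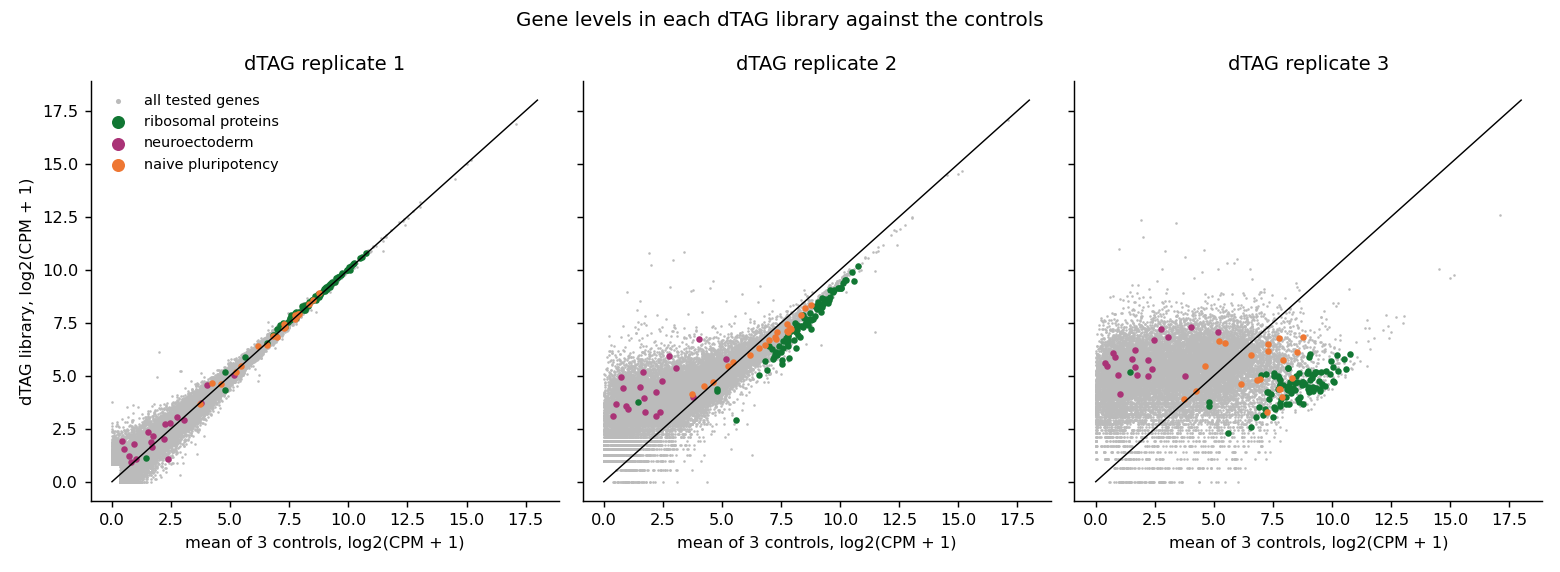
Level of each tested gene in a dTAG library (vertical axis) against the mean of the 3 controls (horizontal axis), both as log2(CPM + 1), one panel per dTAG library, with the line of equal levels; grey points are all 18116 tested genes and coloured points are members of 3 lists. Genes lie along the line in dTAG replicate 1, whereas in dTAG replicate 3 neuroectoderm genes lie above it and ribosomal protein genes below it.

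Pluripotency genes showed no member past the test. Of 20 naive pluripotency genes and 13 core pluripotency genes, 0 passed, genome-wide or adjusted over the list alone. Since the fit recovered 0% of simulated 4-fold changes with background mixed in, this does not show that they were unchanged. Tfcp2l1, a transcription factor of the naive network, had 431 ± 31.9 CPM (SD, n = 3) in the controls and 477, 323 and 114 CPM in dTAG replicates 1, 2 and 3, and Tet2, a methylcytosine dioxygenase, had 367 ± 17.2 CPM (SD, n = 3) and 377, 289 and 69.0 CPM. Dppa5a, an RNA-binding marker of pluripotent cells, had 799.8 ± 32.7 CPM (SD, n = 3) and 874, 414 and 16.001 CPM, and Trim28, a corepressor, had 598 ± 24.7 CPM (SD, n = 3) and 699, 442 and 98.8 CPM. The list medians relative to that of all genes were -1.07 and -1.09 on the log2 scale, and camera called both lists lower (adjusted p = 0.000121 and 0.000883). With an estimated correlation neither call was kept (adjusted p = 0.455 for each).

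The genes of the H2A.Z machinery and of the transcription machinery that acts at the paused polymerase gave a like picture. Srcap and Ep400, the ATPases that load H2A.Z, stood at 239.9 ± 35.5 and 206 ± 26.9 CPM (SD, n = 3) in the controls; Srcap had 238, 259 and 191 CPM in the dTAG libraries and Ep400 had 195, 179 and 129.7 CPM. Polr2a, the largest subunit of RNA polymerase II, had 559 ± 66.2 CPM (SD, n = 3) in the controls and 512, 449.9 and 102 CPM in the dTAG libraries. Supt16, a subunit of the histone chaperone FACT, had 645 ± 26.5 CPM (SD, n = 3) and 597, 496 and 69.0 CPM. None of the 24 H2A.Z genes and remodellers or of the 39 pausing, initiation and elongation factors passed, genome-wide or adjusted over the list alone. The same limit of the fit holds for these genes. Their medians relative to that of all genes were -0.87 and -0.98, with camera adjusted p = 0.000407 and 1.9e-06, and adjusted p = 0.455 for each with an estimated correlation. The 9 other replication-independent histone genes, with H2afx at 763 ± 16.3 CPM (SD, n = 3) in the controls and at 796, 545 and 71.7 CPM, had a median of -0.66 on that scale (camera adjusted p = 0.0272, and adjusted p = 0.455 with an estimated correlation).

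Camera called 11 further lists lower. These were cytosolic ribosomal proteins (89 tested members, median -1.28 relative to that of all genes), nuclear-encoded oxidative phosphorylation (77 members, median -1.18), replication-dependent histones (68 members, median -1.14), ribosome biogenesis (32 members, median -1.03), DNA replication and G1/S (30 members, median -0.95), mitosis and G2/M (30 members, median -1.09), p53 targets (30 members, median -0.77), glycolysis and hypoxia response (26 members, median -1.12), cholesterol synthesis (24 members, median -0.89), the 2-cell-like state (24 members, median -1.20) and nuclear noncoding RNAs (11 members, median -1.21). Their camera adjusted p ran from 2.4e-14 for ribosomal proteins to 0.0312 for p53 targets, with adjusted p = 0.455 for each with an estimated correlation. Genome-wide or adjusted over the list alone, 0 of their members passed. Rpl4, a protein of the large ribosomal subunit, stood at 1723 ± 99.6 CPM (SD, n = 3) in the controls and at 1763, 1169.5 and 64.0 CPM in the dTAG libraries. Top2a, a mitotic topoisomerase, had 722 ± 33.3 CPM (SD, n = 3) and 773, 549 and 96.0 CPM, and the glycolytic enzyme Eno1 had 831 ± 15.1 CPM (SD, n = 3) and 819, 473 and 26.5 CPM. Zscan4f, a marker of the 2-cell-like state, had 1148 ± 225 CPM (SD, n = 3) and 1167, 719 and 38.6 CPM. The Zscan4 genes and the histone genes are families of near-identical copies, so how reads were shared between their members is uncertain. In dTAG replicate 3, where mitochondrial ribosomal RNA took 0.165% of the counts, the median log2 ratios of CPM + 1 to the controls ran from -4.44 for the noncoding RNAs to 0.31 for p53 targets.

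Camera called 6 lists higher, with control levels of 0.875 to 4.55 CPM as list medians over the members in the file. Mesoderm and definitive endoderm genes had a median 2.21 above that of all genes, neuroectoderm genes 1.83 above, Polycomb-bound homeobox genes 1.97 above, primitive endoderm genes 1.60 above, immediate early genes 1.48 above and feeder fibroblast markers 1.46 above. No member passed genome-wide. Adjusted over the list alone, 6 of 18 mesoderm and definitive endoderm genes, 11 of 19 neuroectoderm genes, 10 of 35 homeobox genes, 2 of 27 immediate early genes, 2 of 14 feeder markers and 0 of 18 primitive endoderm genes were higher, and none was lower (edgeR). Camera gave adjusted p from 0.000185 for mesoderm and definitive endoderm to 0.0316 for primitive endoderm, and no call was kept with an estimated correlation (adjusted p = 0.459 for the homeobox genes and 0.455 for each of the others). Ncam1, a neural adhesion molecule, had 15.4 ± 2.53 CPM (SD, n = 3) in the controls and 22.6, 104.6 and 154 CPM in the dTAG libraries, and Evx1, a gene of the primitive streak, had 1.69 ± 0.833 CPM (SD, n = 3) and 1.70, 29.1 and 124 CPM. Junb, an immediate early transcription factor, had 3.97 ± 1.41 CPM (SD, n = 3) and 11.9, 144 and 413 CPM. In the receptor genes, a list added after the data were seen, 44 of 71 tested members were higher when adjusted over the list alone, and 97.1% of all 1430 had a count in dTAG replicate 3. The control median of this list was 0 CPM. Members could thus pass the filter on low counts through dTAG libraries where they are high, which favours higher calls.

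The remaining lists had no camera call. Interferon response genes (21 tested members, median 1.82 above that of all genes) had 1 higher and cell adhesion, actin and TGF-beta targets (22 members, median -0.26) had 2 higher members adjusted over the list alone, whereas formative and primed pluripotency (median 0.51), trophoblast (0.27), FGF-ERK and Wnt response (0.40), germline (-0.18), integrated stress and unfolded protein response (-0.63), heat shock (-1.09) and imprinted genes (-0.63) had 0. Their camera adjusted p lay between 0.0545 for heat shock and 0.914. Camera's direction was lower for FGF-ERK and Wnt response genes although their median and mean log2 fold changes, not set against all genes, were 0.56 and 0.45, and lower for stress response, imprinted, germline and cell adhesion genes although their means were 0.11, 0.07, 0.09 and 0.42. The mitochondrial ribosomal RNAs have only 2 genes and were not tested as a list.

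**Figure D3:**
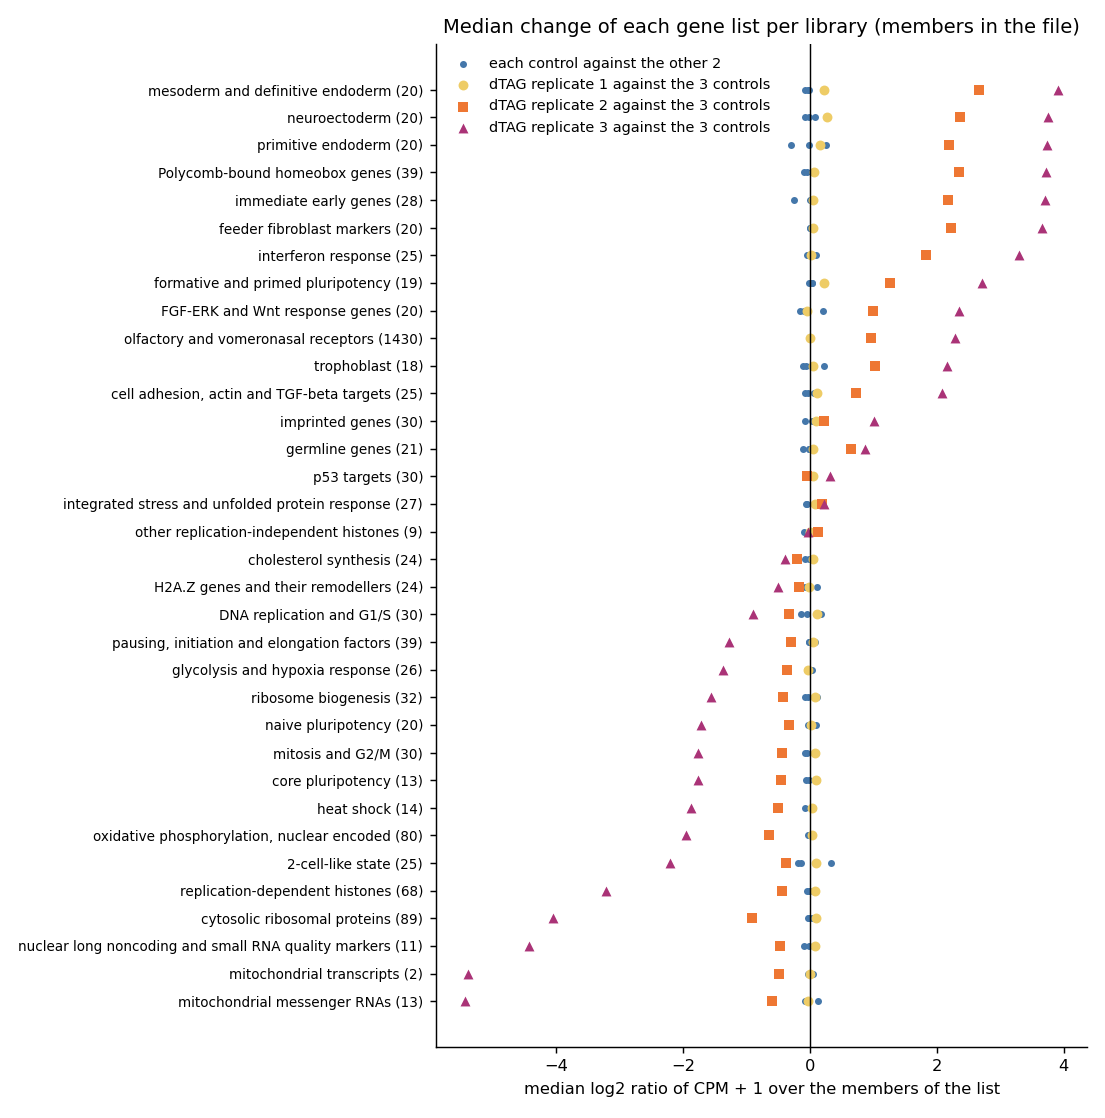
Median log2 ratio of CPM + 1 over the members of each gene list (horizontal axis), for dTAG replicates 1, 2 and 3 against the 3 controls and for each control against the other 2, with the number of members in the file in brackets. For cytosolic ribosomal proteins the medians are 0.09, -0.92 and -4.05 in dTAG replicates 1, 2 and 3, and for neuroectoderm genes they are 0.27, 2.36 and 3.75.

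In dTAG replicate 1 against the 3 controls, 1 of the 31 lists was called by camera, glycolysis and hypoxia response, with a median log2 fold change of -0.12 (adjusted p = 0.00279, and adjusted p = 0.975 with an estimated correlation). These are medians on the TMM scale, on which that of all tested genes was -0.02. The medians of naive and core pluripotency genes were -0.07 and 0.01, those of H2A.Z genes and remodellers and of pausing, initiation and elongation factors were -0.10 and -0.05, and those of mesoderm and definitive endoderm and of neuroectoderm genes were 0.15 and 0.27, each with a camera adjusted p = 0.827. As median log2 ratios of CPM + 1, with no test, the highest were neuroectoderm at 0.27 (controls -0.09 to 0.08), formative and primed pluripotency at 0.22 (-0.03 to 0.03) and mesoderm and definitive endoderm at 0.22 (-0.08 to -0.02), in a library with counts in 23.1% of the receptor genes. By these ratios, with each control set against the other 2, 12 of 32 lists lay above the highest control and 0 below the lowest. On the TMM scale, by contrast, 19 of 31 medians were below 0. Over 8876 genes with at least 10 CPM in the controls, the SD of the log2 ratio was 0.25 for dTAG replicate 1 against the 3 controls. For each control against the other 2 it was 0.26 to 0.29. By more than 2-fold, 31 genes differed in dTAG replicate 1 and 18 to 38 in a control. A mean of 2 libraries is noisier than a mean of 3, which raises the spread of the controls, so these values are not on a like footing. The comparison of dTAG replicate 1 with the controls was chosen after the data were seen, and its dTAG arm of 1 library is assumed to vary like the controls. In simulated genes of at least 10 CPM, with the dispersion trend of these 4 libraries over abundance, changes of 2-fold were recovered in 68% and of 4-fold in 94% of 100 genes each, with 10 false calls. With their common dispersion of 0.105 for every gene, these shares were 0% and 26%. Genes under 10 CPM were not simulated as changed, and each share comes from a single random draw.

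At the level of single genes, 16 were called between dTAG replicate 1 and the controls, 11 higher and 5 lower of 18143 tested (edgeR, adjusted p under 0.05), with 1041 at an unadjusted p under 0.05. The most abundant was Wtap, a subunit of the complex that writes N6-methyladenosine on RNA, named after its values were seen. It had 2840 ± 104 CPM (SD, n = 3) in the controls and 1906 CPM in dTAG replicate 1 (log2 fold change -0.66, SE 0.06, edgeR adjusted p = 1.6e-09). Brd7, a bromodomain subunit of a SWI/SNF chromatin remodeller, likewise named after its values were seen, had 398 ± 3.84 CPM (SD, n = 3) and 252 CPM (log2 fold change -0.74, SE 0.11, edgeR adjusted p = 6.3e-05). The higher genes included Degs2 and Clhc1, of the genes named above, with log2 fold changes of 4.17 (SE 0.75) and 3.63 (SE 0.68) and edgeR adjusted p = 0.00342 and 0.00502. Every higher gene was also above the highest control in dTAG replicates 2 and 3. For Gm21244 (3 and 2 counts) and Gm16404 (2 and 3 counts) this rested on no more counts than a 0 allows. In dTAG replicates 2 and 3, 71.3% and 97.1% of the silent receptor genes had a count. Of the 5 lower genes, Trappc9 (72.0 CPM in the controls, 206 and 174 CPM), Muc19 (10.98, then 36.6 and 64.6 CPM) and Sbsn (6.30, then 8.44 and 37.5 CPM) were above their control means. Among the same 4 libraries, control replicate 1 set against the other 3 gave 11 calls.

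Among genes predicted to hold little background, no difference was called, but the choice of genes leaves out those that are nearly silent in the controls and high in dTAG replicate 3, whatever the cause. Degs2 and Clhc1, called above, are left out in this way, with predicted shares of 98.5% and 96.5%. In the 1631 genes in which counts of the kind seen in dTAG replicate 3 were predicted to make up under 10% of dTAG replicate 2, dTAG replicates 1 and 2 against the controls gave 0 calls (edgeR), with 52 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.157, for Wtap (log2 fold change -0.77, SE 0.10, 95% interval -1.01 to -0.53). Brd7 had -0.27 in this set (95% interval -0.76 to 0.22). The other tools were not run on this set. The middle 95% of log2 fold changes lay between -0.63 and 0.37, and for 1407 of the 1631 genes the 95% interval lay wholly within a 2-fold change in either direction. Nanog had -0.08 (95% interval -0.30 to 0.13), the histone gene Hist2h2aa1 0.09 (-0.10 to 0.28), the ribosomal protein gene Rpl4 0.02 (-0.14 to 0.18) and Eno1 -0.13 (-0.30 to 0.04). The set was chosen after the data were seen, by a predicted share that rests on the control level. Its median control level was 115.5 CPM, against 2.26 CPM over all named genes, and 134 of its genes were under 10 CPM.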

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

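Tests chosen only after the result was seen were those of sequencing depth, of the dTAG treatment, of the calls in dTAG replicate 1 and of the splits. Features without a gene name, used in no comparison except an alternative that kept them, took 6.67% of the counts in dTAG replicate 2 and 14.6% in dTAG replicate 3, against at most 2.37% in a control.

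Counts in silent receptor genes were widespread in dTAG replicates 2 and 3, with 71.3% and 97.1% of the 1430 genes detected. These genes took only 0.239% and 0.811% of the counts in dTAG replicates 2 and 3. Lower depth is argued against as the cause by the controls at full depth, which had counts in at most 17.6% of the receptor genes. Thinning can only lower this share, so the value of at most 4.83% in a control thinned to the total of dTAG replicate 3 adds no separate test. A dTAG effect acting alike in the 3 libraries is also argued against, since dTAG replicate 1 had counts in 23.1% at full depth. Thinned to that total it had counts in 9.93%, again a share that could only fall. An effect that differed between the libraries stays open. Reads from genomic DNA may be a source: such reads would fall on X-linked genes at a lower level than on autosomal ones in a male line, and among silent protein-coding genes the ratio of median counts in dTAG replicate 3 was 0.75. That ratio is at the upper end of the range set beforehand for DNA. Its bootstrap interval of 0.625 to 0.875 reaches past the 0.85 set beforehand, so DNA and another source of such reads cannot be told apart. How evenly the counts lay over genes, which also bears on DNA, was not tested. Counts of silent protein-coding genes in dTAG replicate 3 rose with gene span at a Spearman rho of 0.304. Nectin4, singled out after its values were seen, had 3706 counts there, against a median of 8 in autosomal silent genes. A library of another assay in the place of dTAG replicate 3 was not tested.

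The 11 genes higher in dTAG replicate 1 could be traces of the reads in dTAG replicate 3. The median of their excess in dTAG replicate 1 over their count in dTAG replicate 3 was 0.819, against 0.0913 for the receptor genes, which argues against a plain dilution of that library for the 11 as a set, although 3 of the 11 lay within 3 times the receptor ratio. Of the 4 choices of a lone library among the controls and dTAG replicate 1, only 1 gave as many as 16 calls, dTAG replicate 1 itself, and the highest other gave 11, with too few choices for a share under 0.05. An effect of dTAG stays open and was not tested in a further library free of such reads.

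Wtap was lower in dTAG replicate 1 than in the controls. A shift of all transcripts of its abundance is argued against, since genes at 0.5 to 2 times its level had a median log2 ratio of 0.0289. An effect of dTAG is a candidate explanation: over dTAG replicates 1 and 2 the log2 fold change was -0.77, but the edgeR adjusted p of 0.157 over 1631 genes leaves this open. That value includes dTAG replicate 1, in which Wtap was singled out, so it is not a separate check. In dTAG replicate 2 Wtap had 976 CPM. Another abundant transcript, Cited2, had 133 CPM there against 2813 CPM in the controls, so a low level in that library is not particular to Wtap.

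For the count of 0 genes between the 3 dTAG and the 3 control libraries, all 10 of 10 splits of the 6 libraries gave 0 genes, so the real value and the highest other were both 0, and 10 splits are too few for a share under 0.05.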

How the results depend on the processing

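The settings without dTAG replicates 2 and 3, with little background or with nameless features were chosen after the data were seen. The count of 0 changed genes was also 0 with RLE scaling, library totals, the 1 CPM filter, limma-voom, the robust option, the stricter threshold, glmTreat, nameless features kept, and in genes with under 10% or 20% background, a choice that leaves out genes silent in the controls and high in dTAG replicate 3. No filter on low counts gave 1398 genes, all 1398 higher. DESeq2, also run without that filter, gave 5086, with 5070 higher and 16 lower, and 2007 adjusted p missing. Leaving out 1 library in turn gave 0 to 13222 changed genes, 0 to 8839 higher and 0 to 4383 lower; the upper values came without dTAG replicate 1 and all others were 0. Without dTAG replicates 2 and 3 there were 16 genes, 11 higher and 5 lower. The replicate block gave 13 genes, all 13 higher. Same-numbered libraries had deviations correlated at 0.03, -0.03 and 0.03. Counts in silent genes in dTAG replicates 2 and 3 could hide a shared deviation, so these values cannot decide whether the numbers pair the samples. The cause of the differences between settings was not tested, except that in the fit without dTAG replicate 1 both dTAG libraries hold counts in most silent receptor genes. Of the 31 lists, 22 were called, 0 with an estimated correlation, 0 with fry and 1 without dTAG replicates 2 and 3, where, among the 22, Polycomb-bound homeobox genes and DNA replication genes turned camera's direction, each with a camera adjusted p of 0.827. Apart from these, list results were the same in 252 list and setting pairs, newly past the threshold in 16 and no longer past it in 71, and named genes kept their side of the threshold in 1392 pairs and newly passed in 48. Depth limits dTAG replicates 2 and 3, where a count of 0 allows 1.41 and 1.66 CPM. ERCC and GC settings were not run.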

Other observations

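The values here were singled out after they were seen. Some abundant transcripts were scarce in dTAG replicates 2 and 3 or varied between controls. Cited2, a transcriptional coregulator, had 2813 ± 313 CPM (SD, n = 3) in the controls, 2587 CPM in dTAG replicate 1, 133 CPM, or 284 counts, in dTAG replicate 2 and 43.6 CPM in dTAG replicate 3. Ube3c, a ubiquitin ligase, had 583 ± 62.7 CPM (SD, n = 3) in the controls, 570.0 CPM in dTAG replicate 1, 86.3 CPM in dTAG replicate 2 and 40.3 CPM in dTAG replicate 3. The ribosomal protein gene Rps28 had 185 ± 5.61 CPM (SD, n = 3), then 202, 46.0 and 34.2 CPM in dTAG replicates 1, 2 and 3. Lars2, the mitochondrial leucyl-tRNA synthetase, had 3746, 6235 and 6328 CPM in control replicates 1, 2 and 3, beside 16769.6, 28627 and 25547 CPM of the ribosomal RNA Rn18s.

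In dTAG replicate 1, each of 28 lists was set against 10000 random lists matched on expression. The median log2 ratio of 88 ribosomal protein genes, 0.09, lay above the random medians, whose central 95% ran from 0.02 to 0.07. The controls' own medians for this list ran from -0.04 to 0.03. Replication-dependent histone genes (median 0.08, controls -0.04 to 0.05) were at the 98.8th percentile. Glycolysis and hypoxia genes (median -0.04) were at the 1.09th, within the -0.04 to 0.04 of the controls. These are ratios of CPM + 1. On the TMM scale of the edgeR fit of these 4 libraries, the medians were 0.007 for the ribosomal protein list and -0.002 for the histone list. Camera called neither list there, and its direction was lower for both. The percentiles describe these libraries and are not a test of dTAG.

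The deviations of dTAG replicates 1 and 2 from the shared controls were correlated across 1631 genes with little background at a Pearson r of 0.0962 and a Spearman rho of 0.0599, against 0.183 (0.135 to 0.233) and 0.198 (0.154 to 0.249) in simulated unchanged libraries. The covariance was 0.0125, against 0.0143 simulated (0.0105 to 0.0183). Both correlations lay below their simulated ranges, so the simulation, with 1 dispersion for all genes, does not describe these libraries and decides nothing about a shared deviation. Genes are not independent replicates, and 3 controls are too few to split.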
